A study of Homo sapiens with 4 samples.

How the data were processed

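Total RNA from cultured OSC19 and OSC20 cells and from their tumours in mouse tongue was labelled with Cy3 and hybridised to 1-colour Agilent human arrays, 500 ng of RNA per array, per the labels' protocols. The deposited scanner files hold spot intensity on a linear scale, extracted with Agilent Feature Extraction. The version is 10.7.1.1 per the file headers and 9.5.1.1 per the submitters' processing notes, and the difference was not resolved. The processed signal in those files was background-subtracted and detrended within the array, per the file headers, and not normalized between arrays. The authors' table of processed values also holds intensity on a linear scale. All its columns have a median of 59.6, and each correlated with quantile-normalized scanner values of its own array at r of 0.99997 or more on the log2 scale, so those values were treated as quantile normalized. All 4 arrays were on 1 slide and in 1 scan, so there is no slide or scan batch to test.

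Control spots and spots marked as outliers were left out, and repeated spots of 1 probe were averaged (999 probes had 10 spots each). No spot was saturated. The main values are log2 of the processed signal minus the array's 75th percentile, which was 284, 397, 724 and 851 in cultured OSC19, cultured OSC20, the OSC19 tumour and the OSC20 tumour. Probes were named through RefSeq accessions (25707 probes), current symbols (2182) or synonyms (509); 5724 kept the name in the file. Each of 25984 genes or transcripts was represented by the probe with the highest mean over the arrays. A gene entered a comparison of 2 arrays if its probe was well above background on at least 1 of them, and a dim value was set to the higher of itself and the lowest signal well above background on that array, so differences from it are bounds. The number of arrays limits the precision.

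With 1 array per group, comparisons within a line or within a state are size rules (at least 2-fold), with no p-value. The tests were moderated fits in limma 3.58.1 (R 4.3.3) of cell line plus state on genes well above background on at least 2 of 4 arrays, with Benjamini-Hochberg adjustment, 1 residual degree of freedom and values not raised to the floor. Their p-values set a mean difference over the lines (or states) against its spread, moderated by a prior spread shared by all genes. That prior had 2.80 degrees of freedom against 1 residual, so it carried most of the weight. Where the lines differed little from each other, the p-value rests mainly on the prior. Means ± SD in the text use floored values of the 2 lines. In data simulated over 16427 genes for transplantation across both lines, with spread drawn from the fitted prior and 5000 genes changed, 13.6% of genes changed by 1 (log2) were recovered, 81.8% at 2, 94.9% at 3 and 99.2% at 5, and 3.08% of calls were false. With 200 genes changed and the same spread, 0 were called. With 200 genes changed and each gene's own fitted spread, 0% were recovered at 1, 84% at 2 and 100% at 3 and 5, but 28.3% of the 198 calls were false. The adjusted p-values therefore hold only as far as the prior does.

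Before the data were examined, 20 pathway lists and 9 cell type lists were fixed, along with the comparisons and their tests, the named-gene rule and the first set of alternatives; the tests of explanations came later. Each list's median difference was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these arrays. On 20 random lists of 20 genes in the OSC19 comparison of 17274 genes, 0 lay above percentile 97.5 unaltered and 19 with 1 added on the log2 scale. Genes were named by rule: the 10 highest and 10 lowest by mean difference among genes at least 2-fold different the same way in both lines, the 5 highest and 5 lowest in 1 line where the other differed by under 2-fold, the 5 widest gaps each way among genes in opposite directions, and the 5 highest and 5 lowest between the lines. From each list, up to 4 members with the widest mean difference and 2 with the widest gap between lines were added. Members named as not above background were chosen after their values were seen. Clone and locus identifiers, and names known only from the file, were excluded.

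The alternatives were normexp background correction (offset 50), quantile normalization, centring on the median of probes above background on all arrays, no filter, a stricter filter, the mean of a gene's probes, the authors' values, no floor, a 4-fold threshold, a fit without the second term, an intensity trend in the variance prior, floored values in the fit, an adjusted p under 0.1, and lists without shared members. Removing the trend with probe GC and using the probe nearest the 3' end were added after seeing the data. The GC removal subtracted a median per GC class on each array, so it also recentred the arrays. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No mouse sequence was used here, so probes were not screened for matches to mouse transcripts.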

Results

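Gene expression was measured in OSC19 and OSC20, established human oral squamous cell carcinoma lines, before and after they were grown as tumours in the tongue of nude mice. The stated question was how each line's expression changes from culture to tumour, and so how far the lines differ in their response to the surrounding tissue. Each line gave 1 array of cultured cells and 1 array of tumour tissue, microdissected by laser from 40 frozen slices, each 10 µm thick, taken 12 days after injection. There were thus 4 arrays, 4 groups and 1 array per group, and no difference within a line has a replicate check. Each array held 34122 usable probes. The share of probes well above background was 54.9% in cultured OSC19, 54.2% in cultured OSC20, 63.3% in the OSC19 tumour and 61.9% in the OSC20 tumour. Levels are log2 signals relative to the array's 75th percentile. The spread between repeated spots of 1 probe had a median SD of 0.05 to 0.06 on the log2 scale, which covers spot noise only. Probe positions are on the hg19 build, and whether a probe lies in an exon or an untranslated region was not analysed here.

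Growth as a tumour was accompanied in both lines by far higher signals for some collagen and muscle genes and lower signals for glycolytic genes. COL1A1 and COL1A2, the chains of type I collagen, rose by at least 8.54 and at least 7.37 (log2, mean over n = 2 lines). The matrix proteoglycan gene DCN rose by at least 8.33, the surface antigen gene THY1 by at least 7.23 and the fast muscle troponin gene TNNT3 by at least 6.66. The small heat shock protein gene CRYAB rose by 6.74 ± 0.52 (mean ± SD) and the imprinted non-coding RNA H19 rose by 7.93 ± 3.03. Among the genes that fell, the tight junction gene CLDN11 fell by 4.04 ± 0.04, the stress cytokine gene GDF15 fell by 3.35 ± 0.69, the mitophagy receptor gene BNIP3 fell by 3.30 ± 0.78 and the heme-degrading enzyme gene HMOX1 fell by 3.12 ± 0.39.

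In linear terms, COL1A1 (probe at chromosome 17, 48261509 to 48261568) was 487-fold higher in the OSC19 tumour than in culture and at least 283-fold higher in the OSC20 tumour. DCN was at least 495-fold and at least 209-fold higher, and THY1 at least 174-fold and at least 129-fold higher. CLDN11 (chromosome 3, 170151824 to 170151883) was 16.8-fold lower in OSC19 and 16.1-fold lower in OSC20. A bound, without an SD, is given where a group's probe was not well above background, in which case that side was set to the higher of its own signal and the lowest signal well above background on its array. Also lower were the non-coding RNA SNAR-A3, which fell by 3.41 ± 0.96, the plasma glycoprotein gene ORM1, which fell by at least 3.16, and the transcription factor gene SOX15, which fell by 3.12 ± 0.84. S100A8, OLFM4 and MMP10 were more than 2-fold higher in both tumours, with means of at least 6.57, at least 6.56 and 6.51 ± 3.98, but did not pass the test (limma adjusted p = 0.0617, 0.0578 and 0.0593). MIEF1 and CYP1A1 were lower in both, with means of -4.04 ± 3.53 and at most -3.64, and did not pass either (limma adjusted p = 0.0944 and 0.0821). Of the 3 MIEF1 probes, 1 carried that difference and the others differed by under 2-fold in each line.

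In a limma model with cell line and state as terms, 1529 genes rose and 796 fell with transplantation out of 16427 tested, at an adjusted p under 0.05. COL1A1, DCN, COL1A2, THY1, CRYAB, TNNT3 and CLDN11 each had an adjusted p of 0.0261, and each moved the same way in 2 of 2 lines, which the rule that named them required. The model has 1 residual degree of freedom. The split between the directions depended on scaling: normexp background correction gave 1652 up and 5209 down, and quantile normalization 1282 up and 387 down. The authors' own values gave 1178 up and 314 down. With the probe GC trend removed, an alternative chosen after seeing the data, 1490 rose and 104 fell. That removal also moved the differences of all genes upward (below). Flooring dim values before the fit gave 1543 up and 1625 down.

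By size alone, 3036 genes were at least 2-fold higher and 4771 at least 2-fold lower in the OSC19 tumour than in cultured OSC19, of 17274 measured. In OSC20 the counts were 2475 and 3926 of 16765. With the GC trend removed the splits turned to 3816 and 2182 in OSC19 and 3051 and 1475 in OSC20. That removal also recentred the arrays, moving the median of all genes to 0.03 in OSC19 and 0.02 in OSC20. The turned splits therefore mix a shift of all genes with the GC trend itself. In both lines together, 1817 genes were higher in each tumour, against 431.6 expected from independent lists (2898 × 2370 / 15914), and 2311 were lower, against 1012.1 expected (4345 × 3707 / 15914). Across 15914 genes the differences of the lines correlated with a Pearson r of 0.77 and a Spearman rho of 0.73; genes are not independent replicates. The median difference of all genes was -0.41 in OSC19 and -0.38 in OSC20. Quantile normalization moved these medians by 0.13 and 0.16, so list medians below are given relative to the median of all genes. The share of genes higher among those that differed the same way in both lines was 44.0%, against 53.3% with the authors' values, 77.8% with the GC trend removed and 86.8% at a 4-fold threshold.

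**Figure D1:**
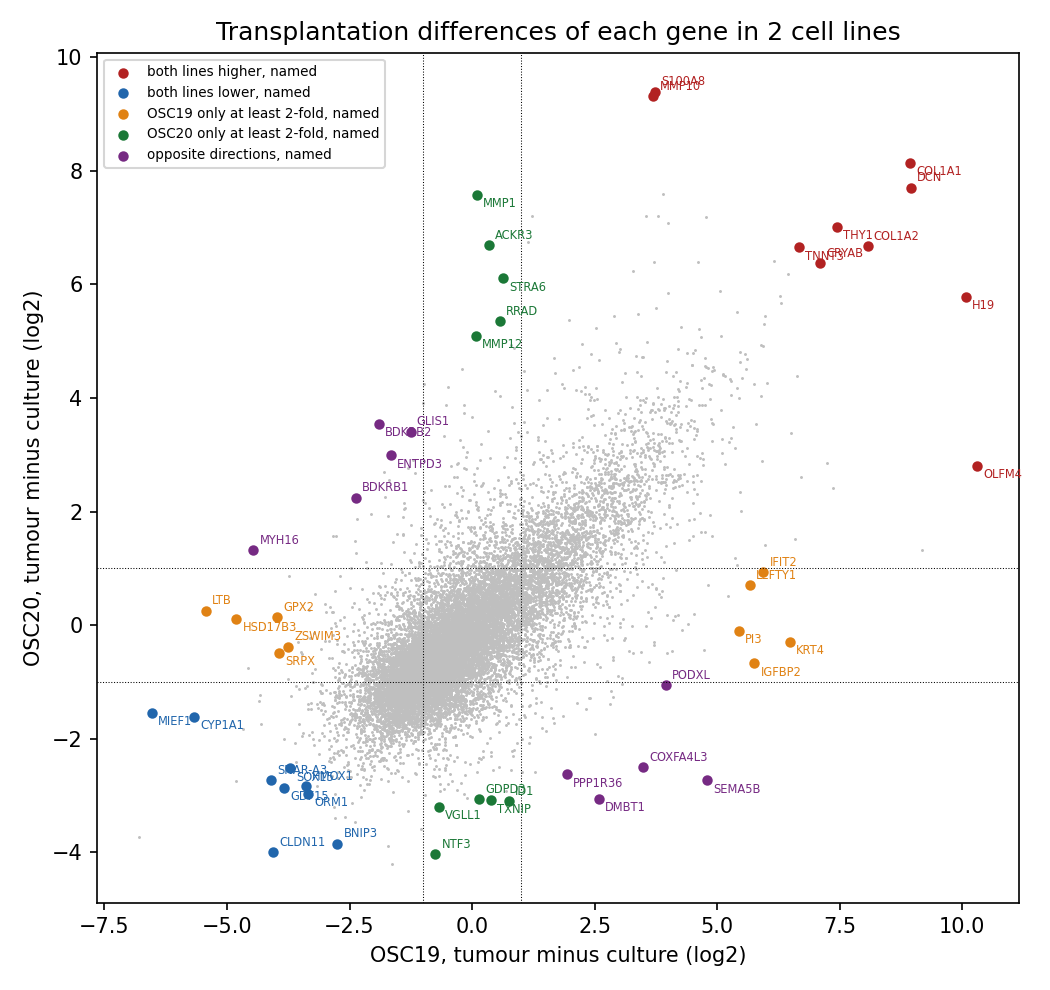
Each grey point is 1 of 15914 genes, with its tumour minus culture difference (log2) in OSC19 on the horizontal axis and in OSC20 on the vertical axis. Dotted lines mark 2-fold differences, and coloured points are genes named in the text. Dim values are floored, so some points are bounds. COL1A1 lies at 8.93 and 8.14, and SEMA5B at 4.80 and -2.73.

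Interferon-stimulated genes stood higher in both tumours, with the larger list median in OSC19. Of 22 measured, 15 were at least 2-fold higher in the OSC19 tumour and 14 in the OSC20 tumour, 11 of them in both, and 0 were 2-fold lower in either. The list median relative to all genes was 2.76 in OSC19 and 1.63 in OSC20, each above all 10000 random lists matched on expression. RSAD2, an antiviral enzyme gene, rose by at least 3.46 on average, on 1 of its 2 probes, and IFI44L rose at least 3.93-fold in OSC19 and at least 41.4-fold in OSC20. OASL was 96.5-fold higher in OSC19 and 2.85-fold higher in OSC20, and IFI44 44.3-fold and 5.07-fold, without passing the test. Of the 22, limma called 4 higher over all genes and 8 when adjusted over the list alone. RSAD2 and IFI44L were among the 4, though dim in both cultures, where the fit used unfloored values. The gap between the lines had a median of 1.29, also above all random lists, with 12 genes at least 2-fold apart toward OSC19 and 5 toward OSC20.

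Signals for keratinocyte genes of the basal layer and of squamous differentiation were higher in both tumours. Probes were not screened against mouse transcripts and no list covered tongue epithelium. Whether mouse tongue RNA contributes to these signals was therefore not tested. Of 14 basal and hemidesmosome genes, 6 were at least 2-fold higher in both lines and 2 lower, with relative medians of 1.30 in OSC19 and 2.14 in OSC20 (percentiles 99.99 and 100). DST, which encodes the hemidesmosome linker dystonin, rose by at least 4.07. The basal keratin genes KRT5 and KRT14 were higher by 6.74 and 4.71 (log2) in the OSC20 tumour but by 1.15 and 1.67 in OSC19, without passing the test. That gap lay in culture, where OSC19 already stood 48.8-fold and 13.1-fold above OSC20. Between the tumours the genes were 1.01-fold and 1.59-fold apart. Limma called 2 of the 14 higher over all genes, 6 higher and 2 lower when adjusted over the list alone, and 4 higher over all genes with the GC trend removed. Of the squamous differentiation list, 4 of 18 genes were higher in both lines and 0 lower, with relative medians of 0.90 and 1.04 (percentiles 99.7 and 99.9), down to 0.74 and 0.55 under other scalings. Under any alternative these medians went down to 0.51 and 0.39. The antimicrobial S100A7 rose by 4.88 ± 0.28 and the mucosal keratin KRT13 rose by 3.98 ± 0.68. Its limma count was 3 higher over all genes, and 4 when adjusted over the list alone or with the GC trend removed. Among 18 junction and epithelial identity genes, 3 were higher and 4 lower in both lines. The desmosomal genes DSG3, DSP and PKP1 rose by 3.96 ± 0.20, 3.16 ± 0.90 and 2.02 ± 0.30, while the tight junction gene CLDN4 differed by -1.44 ± 0.57, on 1 of its 2 probes, without passing. That list's relative medians were 0.23 and -0.06, within the random lists, the latter reaching 0.16 under another scaling, and 3 rose over all genes, with 3 higher and 4 lower when adjusted over the list alone.

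Markers of epithelial-mesenchymal transition were also higher in both tumours, and matrix protease genes were higher in OSC20. Of 12 transition markers measured in both lines, 5 were higher in both, 0 lower and 1 opposite, with relative medians of 2.48 and 1.45 (percentiles 99.91 and 99.95), down to 1.61 and 1.40 under other scalings. Under any alternative these medians went down to 1.36 and 0.98. ZEB1 and TCF4, both transcription factor genes, rose by at least 3.87 (in OSC19 on 1 of 2 ZEB1 probes) and by 3.61 ± 0.34, S100A4 rose by 2.63 ± 0.68 and FN1, the fibronectin gene, rose by at least 3.51 in OSC19 and by 2.09 in OSC20. VIM, the vimentin gene, was 9.80-fold higher in the OSC19 tumour and 1.44-fold higher in the OSC20 tumour. Limma called 5 of 13 higher, both over all genes and adjusted over the list alone. Collagen and smooth muscle markers, which are also made by mesenchymal cells, rose beside this list (below). Of 20 matrix protease and invasion genes, 12 were at least 2-fold higher and 3 lower in OSC20, against 6 higher and 5 lower in OSC19, with relative medians of 1.71 (percentile 100) and 0.26 (percentile 80.5). The gap between the lines had a median of -1.75, below all random lists. MMP7 and MMP13 rose by 5.54 ± 2.17 and 5.38 ± 2.59, and MMP10 was 639-fold higher in OSC20 and 12.9-fold higher in OSC19. Limma called 4 higher and 2 lower over all genes, 5 higher and 2 lower when adjusted over the list alone, and 3 and 0 over all genes with the GC trend removed.

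Glycolytic genes were lower in both tumours. All 15 were at least 2-fold lower in OSC19 and 14 of 15 in OSC20, ALDOC being the exception at 1.55-fold lower. The relative medians of -1.30 and -1.17 lay below all random lists, and ranged up to -0.42 and -0.38 under the other scalings. ENO2, PFKL, GPI and ALDOA fell by 2.59 ± 0.33, 2.25 ± 0.05, 2.16 ± 0.20 and 1.82 ± 0.14. Limma called 8 of 15 lower over all genes, 15 when adjusted over the list alone, and 2 over all genes once the GC trend was removed, when the relative medians stayed low at -0.90 and -1.05 (percentiles 0.53 and 0.01). The amino acid and ER stress list followed, with 8 of 22 genes lower in both lines and 0 higher. Its relative medians were -0.60 (percentile 5.21) and -1.02 (below all random lists), up to -0.27 and -0.64 under other scalings. CHAC1, a glutathione-degrading enzyme gene, fell by 2.23 ± 0.02, and SESN2 and SDF2L1 fell by 1.84 ± 0.44 and 1.71 ± 0.40. There limma called 3 lower over all genes, 10 when adjusted over the list alone and 0 with the GC trend removed, 22 being tested, while the relative medians after that removal were -0.75 and -0.66 (percentiles 0.26 and 0.34). Of 16 hypoxia genes measured in both lines, 5 were lower in both and 0 higher. BNIP3 (above) and DDIT4 fell, DDIT4 by 2.04 ± 0.74, and SLC2A1, the glucose transporter gene, differed by -1.65 ± 0.44, on 1 of its 2 probes, without passing. The relative median was -0.96 in OSC20, below all random lists (up to -0.51 under another scaling), and -0.34 in OSC19 (percentile 26.6), where quantile normalization turned it to 0.04. Limma called 3 lower over all genes, 6 when adjusted over the list alone and 1 over all genes with the GC trend removed (relative medians -0.45 and -1.07). Of 16 NRF2 target genes, 5 were lower and 2 higher in both lines, with relative medians of -0.73 (percentile 0.53) and -0.38 (percentile 12.8), up to -0.47 and -0.20 under other scalings. HMOX1 (above) and OSGIN1 fell, OSGIN1 by 2.08 ± 0.38, while the aldo-keto reductase gene AKR1B10 rose by at least 2.61. Here 1 gene rose and 3 fell over all genes, or 2 and 6 when adjusted over the list alone, or 1 and 1 over all genes with the GC trend removed (relative medians -0.85 and -0.63).

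Proliferation genes moved both ways. Of 25 cell cycle genes, 4 were higher and 9 lower in both lines, CENPF, TOP2A and CCNE2 rising by 3.87 ± 0.06, 2.78 ± 0.21 and 2.12 ± 0.05 and AURKB, which fell by 2.17 ± 0.71, among the lower. The relative median was -0.59 in OSC19 (percentile 7.55), which quantile normalization turned to 0.07, and -0.28 in OSC20 (percentile 40.1). Limma called 4 higher and 6 lower over all genes, and 4 and 12 when adjusted over the list alone. With the GC trend removed it called 3 higher and 0 lower, AURKB no longer among them, and the relative medians were -0.80 and -0.41 (percentiles 0.13 and 7.58). Of 18 ribosomal protein genes, 10 were lower in both lines and 0 higher, but the relative medians of -0.69 and -0.69 lay within the random lists (percentiles 28.7 and 50.7) and turned to 0.24 and 0.23 with quantile normalization. RPS3 fell by 1.55 ± 0.25, and limma called 1 lower over all genes, 14 when adjusted over the list alone and 0 over all genes with the GC trend removed. Of 11 heat shock genes, 2 were higher and 2 lower in both lines. HSPA4L rose by at least 2.36, and HSPA1A, whose sequence is close to that of HSPA1B, was 9.73-fold lower in OSC19 and 2.60-fold lower in OSC20 without passing. The relative medians were -0.61 and 0.03 (percentiles 21.6 and 96.9), the first turning to 0.22 with quantile normalization, and with the GC trend removed they were -1.21 and -0.09 (percentiles 0.03 and 90.3). Limma called 1 higher over all genes and 3 higher and 5 lower when adjusted over the list alone.

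Inflammatory and NF-kB genes stood at a relative median of 1.69 in OSC19 (above all random lists) and 0.38 in OSC20 (percentile 77.0). In OSC19, 12 of 21 were at least 2-fold higher and 2 lower, and in OSC20 2 of 16 were higher and 1 lower. IL1B was 10.1-fold lower in the OSC19 tumour and 1.20-fold higher in the OSC20 tumour. IL6 was 3.17-fold higher in OSC19 and 3.31-fold lower in OSC20. BIRC3 and CXCL1 rose by 4.40 ± 2.14 and 1.58 ± 0.28 (in OSC19 on 1 of 2 CXCL1 probes), and limma called 3 of 18 higher over all genes, 3 when adjusted over the list alone and 1 over all genes with the GC trend removed. Cholesterol synthesis genes stood at 0.72 in OSC19 (percentile 99.8) and 0.09 in OSC20 (percentile 90.2), and at 0.45 and 0.16 with the GC trend removed. HMGCS1, of the mevalonate pathway, rose by 2.72 ± 0.08 as the 1 call of 21, over all genes and adjusted over the list alone. TGF-beta and YAP targets stood at 0.70 and 0.20 (percentiles 99.6 and 91.6), but at 0.32 and -0.00 with the GC trend removed, within the random lists (percentiles 96.5 and 69.8), and down to 0.37 and 0.11 under other scalings. SKIL and LTBP2 rose by 3.27 ± 0.25 and at least 2.24, CCN1 fell by 2.24 ± 0.08, and these were the 2 higher and 1 lower calls on either adjustment. Notch pathway genes stood at 0.35 and 1.02 (percentiles 88.7 and 98.2), the latter down to 0.61 under another scaling, with NOTCH3, which rose by 2.32 ± 0.92, among 2 of 13 called higher on either adjustment (3 with the GC trend removed). NOTCH3 is also a member of the smooth muscle and pericyte list, which rose (below). HEYL, also called over all genes, was dim in both cultures, where the fit used unfloored values. Its floored differences were -0.68 in OSC19 and 1.47 in OSC20. Antigen presentation genes stood at -0.09 and 0.24 (percentiles 80.3 and 99.5), reaching 0.26 and 0.76 under other scalings. HLA-DRA, the 1 of 18 called over all genes, was 30.4-fold higher in the OSC20 tumour but at least 1.74-fold higher in the OSC19 tumour. It was dim in cultured OSC19, where the fit used its unfloored value. Limma called 0 when adjusted over the list alone or with the GC trend removed. Immediate early genes stood at -0.22 and -0.00 (percentiles 45.1 and 66.7), reaching 0.47 and 0.13 under other scalings, and FOSL1 and IER3 fell by 2.06 ± 0.17 and 2.01 ± 0.71, 2 of 16 being called lower over all genes, 1 when adjusted over the list alone, and 1 higher and 1 lower over all genes with the GC trend removed. EGFR ligands and receptors stood at 0.28 and -0.13 (percentiles 72.2 and 30.6), with 0 of 10 called by limma on either adjustment.

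**Figure D2:**
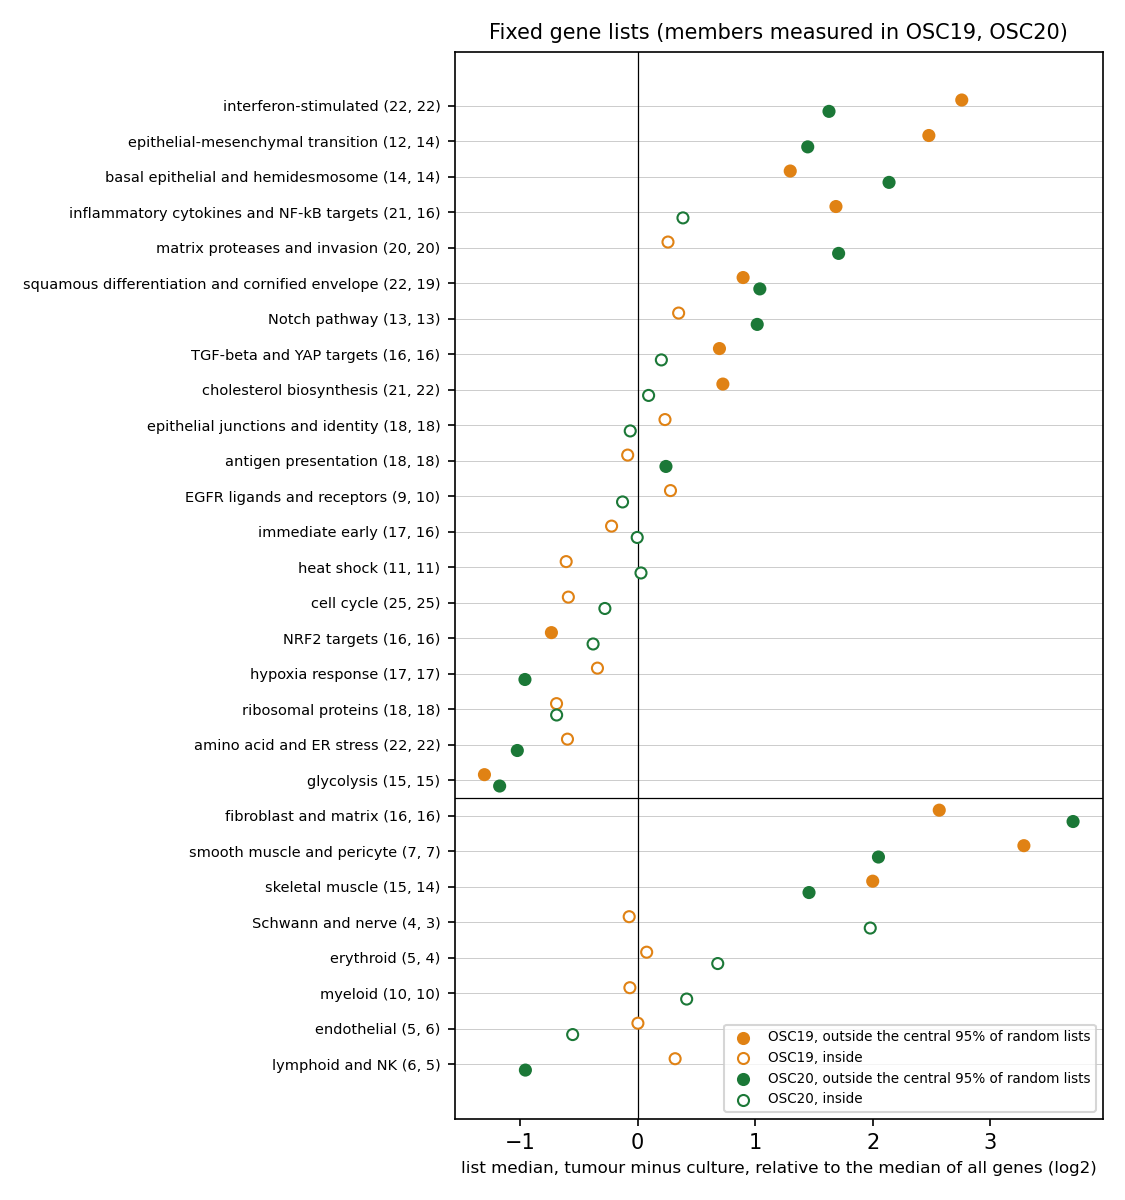
Each row is a gene list fixed before the data were examined, with the number of members measured in each line; the axis is the list's median tumour minus culture difference (log2) relative to the median of all genes. Filled points lie outside the central 95% of 10000 random lists. Interferon-stimulated genes lie at 2.76 and 1.63 and glycolytic genes at -1.30 and -1.17. The cell cycle, hypoxia, heat shock and ribosomal medians of OSC19, and the ribosomal median of OSC20, turn positive with quantile normalization. The antigen presentation median of OSC19, the junction median of OSC20 and the immediate early medians of both lines turn positive under another scaling.

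Markers of other cell types of the tongue were among the genes that differed most between tumour and culture. Of the fibroblast and matrix list, 9 of 15 genes were higher in both lines and 0 lower, with relative medians of 2.57 and 3.70 above all random lists, down to 2.28 and 2.72 under other scalings. Under any alternative these medians went down to 1.29 and 2.72. Limma called 10 of 17 higher over all genes, 11 when adjusted over the list alone and 8 over all genes with the GC trend removed. Of the skeletal muscle list, 7 of 13 were higher in both lines, with relative medians of 2.00 and 1.46 (percentiles 100 and 99.9), down to 0.73 and 1.07 under other scalings and to 0.22 and 0.34 under any alternative, and 7 of 14 were called higher on either adjustment. ATP2A1, the calcium pump gene of fast muscle, MYL1 and TNNI2 rose by at least 6.05, at least 5.62 and 5.51 ± 1.59, ATP2A1 on 2 of its 3 probes. Of the smooth muscle and pericyte list, 4 of 7 were higher in both lines, with relative medians of 3.29 and 2.05 (percentiles 100 and 99.9), down to 1.65 and 1.72 under other scalings. Under any alternative these medians went down to 1.65 and 0.91. ACTA2 rose by 4.26 ± 0.53. TAGLN was higher by at least 4.44 on 1 of its 2 probes, while the probe nearest the 3' end differed by 0.53 in OSC19 and -0.30 in OSC20. Limma called 4 higher over all genes, 6 when adjusted over the list alone and 5 over all genes with the GC trend removed. The complement gene C1QB rose by at least 6.29 and the hemoglobin gene HBA2 rose by 4.60 in OSC19 and at least 6.40 in OSC20, on 2 of its 3 probes, the other being at least 2-fold lower in OSC20. Other members were not well above background on any array, among them COL3A1, POSTN, PDGFRB, ACTA1, CKM and C1QA.

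The other marker lists did not stand apart in both lines. Myeloid markers lay at relative medians of -0.07 and 0.42 (percentiles 36.1 and 65.5), the latter down to -0.09 under another scaling, with 1 of 11 called higher over all genes and 3 higher and 3 lower when adjusted over the list alone. Endothelial markers lay at 0.00 and -0.55 (percentiles 41.9 and 6.56), the former down to -0.39 under another scaling. TIE1 rose by at least 2.56 and EGFL7 fell by 2.62 ± 0.09, the only calls of 4 tested, on either adjustment, and with the GC trend removed limma called 1 higher and 0 lower. Erythroid markers lay at 0.08 and 0.68 (percentiles 29.7 and 59.2), the former down to -0.36 under another scaling, with 1 of 4 called higher over all genes, and 2 when adjusted over the list alone or with the GC trend removed. Lymphoid markers lay at 0.32 and -0.96 (percentiles 52.2 and 1.29) and had 0 of 6 called by limma on either adjustment. Schwann cell and nerve markers lay at -0.07 and 1.98 (percentiles 33.3 and 95.0), the latter down to 0.94 under another scaling, with 0 of 4 called over all genes and 1 higher when adjusted over the list alone. Only 2 adipocyte markers were measured, CFD at -1.41 ± 0.81 and CIDEC at -0.41 ± 0.01, too few for a percentile, and limma called 0 of 2 on either adjustment.

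Some large differences were seen in OSC19 while the OSC20 difference, with dim values floored, was under 2-fold. The mucosal keratin gene KRT4 was 89.5-fold higher in the OSC19 tumour, the interferon-induced IFIT2 61.5-fold, the IGF-binding protein gene IGFBP2 at least 54.1-fold, the Nodal antagonist gene LEFTY1 at least 50.7-fold and PI3, the elafin gene, 43.6-fold. In OSC20, IFIT2 and PI3 differed by 0.93 and -0.10 (log2). KRT4, IGFBP2, LEFTY1 and HSD17B3 were not well above background in cultured OSC20, so a rise in that line is not excluded. Unfloored levels went from -4.72 to -3.43 for LEFTY1 and from -6.12 to -4.03 for HSD17B3. Lower in the OSC19 tumour were the lymphotoxin gene LTB, 43.3-fold, the steroid dehydrogenase gene HSD17B3, 28.1-fold, the glutathione peroxidase gene GPX2, 15.7-fold, SRPX, at least 15.3-fold, and ZSWIM3, 13.4-fold. In culture LTB and HSD17B3 already stood 19.7-fold and at least 48.1-fold higher in OSC19, and between the tumours they were 2.63-fold and 1.59-fold apart. GPX2, SRPX and ZSWIM3 were instead lower in the OSC19 than the OSC20 tumour, 4.52-fold, at least 23.4-fold and 11.2-fold. With 1 array per group, whether these differences depend on the line was not tested. Whether mouse tongue RNA contributes to the KRT4 and PI3 signals was not tested either.

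In OSC20 the interstitial collagenase gene MMP1 was 191-fold higher in the tumour than in culture, against 0.10 (log2) in OSC19. The chemokine receptor gene ACKR3 was at least 104-fold higher, STRA6, the receptor for retinol-binding protein, at least 69.1-fold, the small GTPase gene RRAD 40.9-fold and the macrophage elastase gene MMP12 at least 34.2-fold. MMP12 was not well above background in cultured OSC19, so a rise there is not excluded. Between the tumours, MMP1 and MMP12 were 40.5-fold and 36.3-fold higher in OSC20. ACKR3, STRA6 and RRAD were 1.58-fold, 2.72-fold and 1.96-fold apart between the tumours. In culture those genes already stood at least 129-fold, at least 16.3-fold and 14.1-fold higher in OSC19. Lower in the OSC20 tumour were the neurotrophin gene NTF3, 16.4-fold, the TEAD cofactor gene VGLL1, 9.19-fold, ID1, an inhibitor of basic helix-loop-helix factors, 8.55-fold, the thioredoxin-interacting protein gene TXNIP, 8.50-fold, and GDPD3, at least 8.36-fold. In OSC19 these lower genes differed by -0.75, -0.68, 0.75, 0.38 and 0.14 (log2). NTF3 and ID1 stood 17.9-fold and 6.23-fold higher in cultured OSC20 than in cultured OSC19, and between the tumours they were 1.84-fold and 2.31-fold apart. VGLL1, TXNIP and GDPD3 were instead further apart between the tumours, 4.40-fold, 6.01-fold and at least 4.22-fold, than in culture.

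Opposite directions were rare. Only 89 genes were at least 2-fold different in opposite directions, 43 higher in the OSC19 tumour and lower in the OSC20 tumour, and 46 the other way (10 and 17 with normexp background correction). SEMA5B, a semaphorin gene, was at least 27.9-fold higher in the OSC19 tumour and at least 6.65-fold lower in the OSC20 tumour. DMBT1, a mucosal scavenger receptor gene, was 6.01-fold higher and 8.36-fold lower, and PODXL, the podocalyxin gene, 15.5-fold higher and 2.08-fold lower. The bradykinin receptor genes BDKRB1 and BDKRB2 went the other way, 5.17-fold and 3.74-fold lower in the OSC19 tumour and at least 4.74-fold and at least 11.7-fold higher in the OSC20 tumour. In culture they stood at least 12.6-fold and at least 28.1-fold higher in OSC19, and between the tumours 1.95-fold and 1.56-fold apart. SEMA5B, DMBT1 and PODXL were instead lower in cultured OSC19 than in cultured OSC20 and higher in the OSC19 tumour than in the OSC20 tumour.

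The lines themselves differed in genes of varied function, named here by their mean difference over both states. The cancer-testis genes MAGEA2B and MAGEB2 were higher in OSC19, by at least 7.97 and at least 6.23 (log2, mean over n = 2 states), as were HCLS1, a hematopoietic signalling gene, by 7.85 ± 0.48 (mean ± SD), the imprinted SNURF by at least 6.33 and the lectin gene ZG16B by at least 6.22. MAGEA2B has a near-identical copy, MAGEA2, which its probes may not separate. Lower in OSC19 were the glycosyltransferase gene GALNT14, at -7.63 or below, PLBD1 at -7.43 or below, the ciliary gene CFAP300 at -7.40 or below, the amino acid transporter gene SLC38A5 at -7.37 ± 0.69 and HPDL at -7.29 or below. All 10 passed the limma test of the line term, with adjusted p from 0.0241 to 0.0342 and the same direction in 2 of 2 states. The rule that named them required that shared direction. Across all genes that test called 167 higher and 240 lower in OSC19 of 16427.

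In culture, 1724 genes were at least 2-fold higher and 1946 at least 2-fold lower in OSC19 than in OSC20, of 15859 measured, and between the tumours 2015 and 2272 of 17593. Of these, 771 were higher in OSC19 in both states and 926 lower in both, while 34 and 61 turned direction. Across 15327 genes the line differences of the states correlated with r = 0.65 and rho = 0.54. Inflammatory and NF-kB genes were higher in OSC19 over both states, with a list median of 2.57, above all random lists, and limma called 5 of 18 higher over all genes and 12 when adjusted over the list alone. CXCL1 was among them, at 3.30. Antigen presentation genes were lower in OSC19, with a median of -1.14, below all random lists, and 2 of 18 were called lower over all genes and 5 when adjusted over the list alone. NRF2 targets were lower too, with a median of -1.04, below all random lists; 1 of 16 was called lower over all genes, AKR1B10, at -3.91 or below, and 4 when adjusted over the list alone. VIM differed by -5.12 (OSC19 minus OSC20, log2, mean over both states), without passing.

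The differences between tumour and culture varied with the base composition of the probe. Among 13422 genes well above background on all arrays, they correlated with the number of G and C bases in the 60-base probe with rho = -0.35 in OSC19 and -0.39 in OSC20. The median was 0.10 and 0.02 for probes with up to 21 such bases, and -0.97 and -0.94 for probes with over 30. Culture pellets and microdissected tissue were prepared differently, so sample handling and state cannot be told apart.

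**Figure D3:**
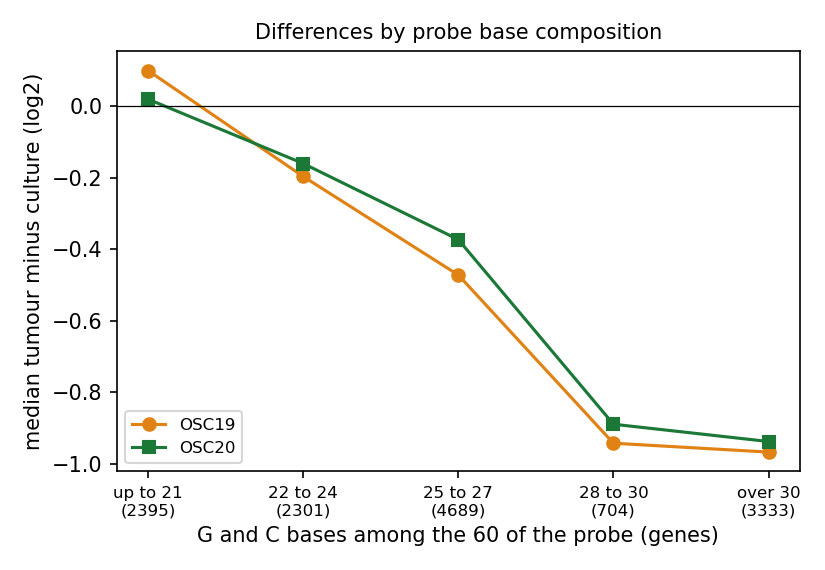
Median tumour minus culture difference (log2) in each line for genes grouped by the number of G and C bases in their probe, with the number of genes in parentheses. OSC19 goes from 0.10 to -0.97 and OSC20 from 0.02 to -0.94.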

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

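The tests of probe distance from the 3' end and of base composition as the whole cause were chosen after related results were seen; the others were fixed before their results.

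Named genes and list members at least 2-fold different in opposite directions in the lines stand out, and with 1 array per group the differences between lines were not tested. As the tumour minus culture difference (log2) of OSC19 minus that of OSC20, SEMA5B stood at 7.54, COXFA4L3 (a gene of the cytochrome c oxidase family) at 5.99, DMBT1 at 5.65, PODXL at 5.01 and PPP1R36 at 4.57. EPGN, an EGFR ligand gene, stood at 4.15, the muscle myosin gene MYH1 at 3.87 and the cytokine gene IL6 at 3.39. The other way, MYH16 stood at -5.78, BDKRB2 at -5.45, GLIS1 at -4.66, ENTPD3 at -4.65, BDKRB1 at -4.62 and COL6A2 at -3.62. SNAI1, an epithelial-mesenchymal transition factor gene, stood at -3.13, AKR1C1 at -3.01, NGFR at -3.00 and DLL1 at -2.95. Some gaps lay mainly in culture: between the tumours COXFA4L3, BDKRB2 and ENTPD3 were 1.12-fold, 1.56-fold and 1.07-fold apart. Others lay also in the tumours, where SEMA5B and MYH16 were at least 47.4-fold and 8.27-fold apart. The values of SEMA5B, PPP1R36, EPGN, MYH1, BDKRB2, GLIS1, ENTPD3, BDKRB1, COL6A2 and NGFR are bounds, since a probe was not well above background in at least 1 group, so each gap is at least that wide.

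Muscle and fibroblast genes were far higher in both tumours, the 16 list members at least 2-fold higher in both having a median of 5.33 (log2). The trend with probe GC is too small to account for this, with class medians from 0.10 to -0.97 in OSC19 and from 0.02 to -0.94 in OSC20. Once the trend was removed, which also recentred all genes upward, the members' median was 5.61. These members were picked for their rise, so that test could scarcely have come out otherwise. RNA of the mouse tongue binding to some human probes may contribute and stays open. The rise was uneven: COL3A1, POSTN, PDGFRB, ACTA1 and CKM were not well above background on any array, while COL1A1, DCN, TNNT3 and MYL1 rose far. Binding to only some probes would go with that, but these members were chosen after their values were seen. In a tumour, 16 of 23 muscle and 17 of 21 fibroblast members on the array were well above background. Among genes with several probes and 1 at least 16-fold higher in both tumours, another probe was not well above background on either tumour in 2 of 4 muscle and fibroblast genes (TTN and ATP2A1) against 4 of 29 others (Fisher's exact test, one-sided, p = 0.142), too few genes to decide. Expression by the human cells themselves was not tested and stays open too.

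Interferon-stimulated genes were higher in both tumours, with a larger list median in OSC19. The trend with probe GC cannot account for this, because the smaller of the list's relative medians was 1.61 once it was removed. Mouse RNA could contribute: the median gap between lines was 1.29 for the interferon list and 0.59 for the raised muscle and fibroblast genes, a difference of 0.69 with a 95% bootstrap interval from -1.10 to 1.62, which leaves it open. A response of the human cells to the host tissue was not tested and stays open.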

How the results depend on the processing

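Removing the GC trend, which also recentred the arrays, and using the probe nearest the 3' end were chosen after seeing the data. The cause of each change below was not tested, unless stated. Of 102 alternative values of the 8 counts and the correlation, 79 stayed within the limit of 1.5 times (or 0.1 for the correlation, which ranged from 0.74 to 0.77). Genes changed by transplantation numbered 2325, against 6861 with normexp, 4624 with genes above background on every array (fewer tested), 1492 with the authors' values, 258 without the line term, 5868 with an intensity trend, 7178 at an adjusted p under 0.1 and 0 without the filter (limma; 12545 at an unadjusted p under 0.05). Of the 1529 that rose, 975 also rose with normexp, 696 with genes above background on every array and 1335 with the GC trend removed, and of the 796 that fell, 795, 713 and 104 did. Genes differing between lines numbered 407, against 251 with genes above background on every array, 18 without the state term, 1246 with an intensity trend, 1080 at an adjusted p under 0.1 and 0 without the filter (3864 unadjusted). A 4-fold threshold, stricter by construction, left 2222 of 7807 genes in OSC19, 1332 of 6401 in OSC20, 842 of 4128 the same way, 4 of 89 in opposite directions, 971 of 3670 between cultures and 1252 of 4287 between tumours. It also turned the split, with 1463 higher and 759 lower in OSC19, 988 and 344 in OSC20, and 731 and 111 the same way in both. Normexp gave 27 opposite genes, 2005 between cultures and 2748 between tumours. Opposite genes numbered 51 above background on all arrays and 149 without the floor. Of 56 list medians under up to 11 alternatives, 441 values moved by less than 1 SD of random lists and 175 by more, and none outside the central 95% of random lists changed sign. Of the named genes' values, 1889 moved by less than the SD between lines (or states), 247 by more and 2 changed sign, both with the mean of a gene's probes: NCAM1 to -0.72, from 2.80 (floored), and the line gap of ITGB2 to -0.0636, from 1.87. The main fit compares tumour and culture within each line. Signal over background limits the genes given as bounds.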

Other observations

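Genes with several probes differed in how far those probes went together; the examples here were chosen after their values were seen. The nuclear pore gene TPR had 1 probe that went from -3.26 to 3.05 (log2 level) in OSC19 and from -2.88 to 2.79 in OSC20, while its other probe was not well above background in either culture and reached only -4.39 in the OSC19 tumour. PHIP had both probes far higher in the tumours, 1 going from -3.40 to 3.05 and the other from -4.66, not well above background, to 0.88 in OSC19. MKI67, the proliferation marker of the cell cycle list, was higher on all 3 of its probes, for example from -0.97 to 1.21 in OSC19 and from -0.10 to 1.31 in OSC20, beside a cell cycle list with more genes lower than higher.

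The fall of tumour minus culture differences with probe GC was weighed on 2635 genes with a pair of probes well above background on every array; the slope and 3' end tests were chosen after related results were seen. Base composition of the probe cannot be the whole cause: the slope on GC between probes of 1 gene was at most 0.174 of the slope across the same genes (95% interval 0.10 to 0.25 in OSC20). The pair difference followed the pair's GC gap with rho = -0.0962 in OSC19 and -0.0746 in OSC20. Both lay just above -0.1, the outcome set beforehand for no contribution. The ratio of slopes had 95% intervals from 0.10 to 0.23 in OSC19 and 0.10 to 0.25 in OSC20. Differences within genes thus did vary weakly with GC. Whether base composition contributes stays open, since the GC gap of a pair was not separated from its position. Probes of a pair differed by position: relative to the 3' probe, the 5' probe had the lower tumour minus culture difference, with a median of -0.226 in OSC19 and -0.179 in OSC20. Position was not separated from the GC gap of the pair in that test. The test was written for the opposite direction, so it does not exclude that distance from the 3' end, as with poorer RNA in the tumour samples, contributes to the fall with GC, and this stays open. Differences in RNA handling between pellets and microdissected sections, and regulation of genes that differ in GC, may each play a part and were not tested.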
